A study of Rattus norvegicus with 24 samples.

How the data were processed

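Bulk RNA sequencing of 24 skin samples was analysed, 6 in each of 4 groups defined by the injection site, intradermal (ID) or subcutaneous (SC), and by what was injected, gel or saline. Per the labels' protocols, total RNA from dorsal skin was extracted with Trizol, treated with DNase and made into stranded mRNA libraries. The study text gives paired-end sequencing on an Illumina HiSeq X system and sampling at day 7. Groups were taken from the sample titles, and the columns were joined to samples by the library names in the labels. In the deposited table the libraries of ID saline stand beside those of SC gel, and those of SC saline beside ID gel, an order that was not used for grouping. The numbers of the replicates were not treated as pairs.

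The deposited table holds, per the file headers, a read count and an FPKM value for each gene and library. Per the submitters' processing notes the tools were FastQC 0.11.2, Trimmomatic 0.36, StringTie 1.3.3b and DESeq2 1.12.4, named without role or order. The aligner, the counting program, its strand setting and its handling of reads shared between genes are not given in the sources used here. The counts were whole numbers, and the deposited FPKM values equalled each count divided by the gene length in kilobases and by the total of the library and scaled by a constant, within 0.001%. The library sums were 14024353 to 18821730, and the totals implied by the FPKM values lay within 0.032% of them. The notes name the build Rnor_6.0, but 47 genes lie on sequences with mRatBN7.2 names and the last gene of chromosome 1 ends at 260398790, so coordinates are given as in the file without a build.

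The table held 23095 genes, of which 3638 had 0 counts in all libraries. Symbols came from the file for 19480 genes and from the supplied RefSeq table for 331 more, and 2779 stayed without one. Where several genes shared a symbol (285 genes), the gene with most counts kept it and the others were called by their gene identifiers. Genes whose name and Entrez number disagreed (505) were left out of lists and of named results. The table came with 1 line emptied, which is not reported here.

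Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. The default filterByExpr filter by group kept 14763 genes, and TMM factors ran from 0.845 to 1.224. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 24 libraries (20 residual degrees of freedom) and tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The contrasts were ID gel against ID saline, SC gel against SC saline, the difference between these effects, and ID saline against SC saline. Fitted log2 fold changes carry the standard error implied by the test, |log2 fold change| over the square root of F, and levels are means of CPM with TMM factors. Folds against a group without counts were bounded at a floor of 3 counts over the group. Floors and the bounds from them cover counting error only.

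Marker lists for skin, immune, matrix and injury genes (33 lists with 678 entries, 43 of them without a match) were tested with camera on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, for lists of at least 5 tested genes, adjusted over the lists of a contrast. Calls within a list were also adjusted over the list alone. Setting genes at 0 in a group to their bound left the median of each list as printed at both sites. Named genes were the 6 largest rises and 6 largest falls per site with adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between groups. For the other contrasts they were 5 and 5 by the same limits, but overlap between groups was allowed. A panel of 13 genes and up to 3 genes per direction from each list were named as well. The groups, contrasts, tests, lists, panel, rule for named genes and most of the other settings were set before the data were examined.

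The other settings fixed then were the DESeq2 1.42.0 Wald test, limma voom with quality weights, RLE factors, no filter, a filter of 10 counts in 12 libraries, only the groups of the contrast, a replicate block, robust empirical Bayes, limma on log2 FPKM with pseudocounts of 1 and 0.1 for genes with at least 1 FPKM in 6 libraries, a limit of 1 log2 unit, each library left out in turn, and for lists an estimated correlation or fry. Fry asks whether a list changed at all, and camera whether it changed more than the other genes. Settings added after seeing the results were gel replicates 1 to 3 or 4 to 6 alone, the saline groups exchanged, and the named genes with each library left out. Each count of genes was compared with 100 splits of the same libraries into groups of the same sizes.

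The method was tested on simulated data, negative binomial counts with the means, dispersions and library totals of these data, in which 200 genes were changed in 1 group. At 1.5-fold it found 38.8% of them for ID, 47.8% for SC, 20.9% for the difference and 47.8% for saline, at 2-fold 74.6%, 88.1%, 65.7% and 85.1%, and at 4-fold 90.9%, 93.9%, 93.9% and 97%. The false calls numbered 5, 4, 5 and 9. All other genes had the same mean in the 4 groups, whereas in the data 73.6% of genes changed at ID and 50.8% at SC. The simulation therefore does not test how the scaling affects the direction of calls in these data. No pair of replicates lay within counting noise, the lowest chi-square per degree of freedom being 5.64.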

Results

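RNA was sequenced from the skin of Sprague-Dawley rats 7 days after an injection of a biodegradable polymer gel or of saline, placed intradermally (ID) or subcutaneously (SC). The 4 groups held 6 libraries each, 24 in all, with 14024353 to 18821730 counts per library. The labels do not say that replicates came from separate animals, so every p-value here measures the spread between these samples only. Coordinates are those in the file. The submitters' notes name the build Rnor_6.0, whereas 47 genes lie on unplaced sequences that carry mRatBN7.2 names, so the build of the coordinates is uncertain. Values are mean CPM, counts scaled to a common library total, ± SD, or log2 fold changes ± SE, with n = 6 per group unless stated.

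Gel and saline libraries parted along the first principal component, which held 63.8% of the variance, with scores of -86.46 to -62.99 in saline and 1.7 to 149.5 in gel. The second component held 18.6% and parted ID gel (12 to 72.81) from SC gel (-82.07 to -52.81). The lowest correlation between replicates was 0.972 in ID saline, 0.967 in SC saline, 0.933 in ID gel and 0.936 in SC gel. Replicates 1 to 3 parted from replicates 4 to 6 of the same gel group, with a gap of over 0.5 log2 units, for 335 genes in ID gel and 214 in SC gel, where the other 9 splits of 3 against 3 parted at most 244 and 102. In 53 of these genes both sites parted in the same direction. For that reason values from each set of replicates stand beside some pooled values below.

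**Figure D1:**
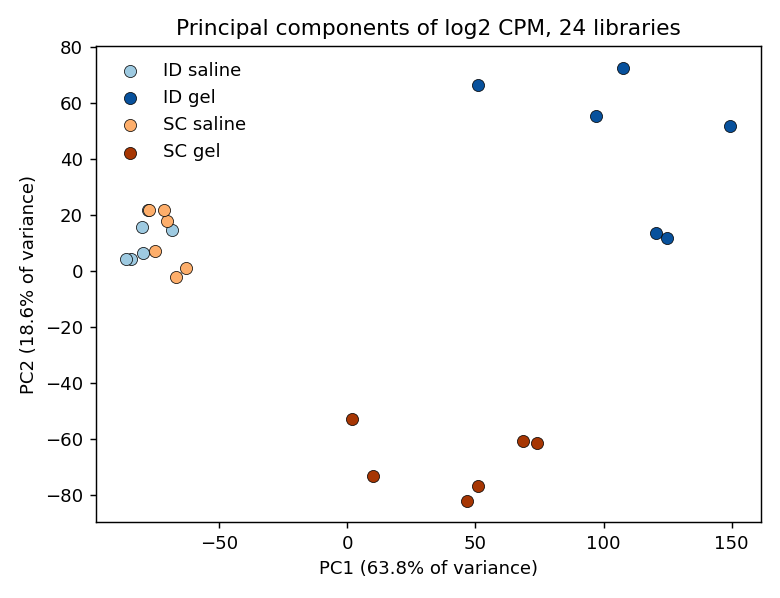
Scores of the 24 libraries on the first component (x axis, 63.8% of the variance) and the second (y axis, 18.6%) of log2 CPM, coloured by group.

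The first comparison, ID gel against ID saline, asked how skin responded to gel placed in the dermis. Macrophage, cytokine and interferon response genes rose, while hair, epidermal and skeletal muscle genes fell. For these lists adjusted p was 0.49 to 0.494 with an estimated correlation. Cd68, a lysosomal glycoprotein of macrophages, stood at 1210 ± 228 CPM in gel and 37.5 ± 13.7 in saline, a rise of 5.01 ± 0.41 log2 units (32.3-fold, adjusted p = 1.67e-10). Nos2, the inducible nitric oxide synthase, rose by 7.10 ± 0.49 log2 units from 1.18 ± 0.542 to 161 ± 80.4 CPM (adjusted p = 1.46e-11). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 10868 of 14763 tested genes changed (73.6%), 5400 higher and 5468 lower. Of these, 2288 rose and 2992 fell by at least 1 log2 unit.

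The largest rises at this site included Acod1, Mmp9 and Ccl9. Acod1 (chromosome 15, 79871827 to 79880529), the enzyme that makes itaconate in activated macrophages, reached 234 ± 100 CPM from 0.0456 ± 0.0567, a rise of 12.16 ± 0.89 log2 units. Mmp9 (chromosome 3, 153683858 to 153692120), a gelatinase, reached 1130 ± 413 from 0.68 ± 0.606 CPM (10.69 ± 0.90 log2 units), and the chemokine Ccl9 reached 370 ± 215 from 0.31 ± 0.189 CPM (10.21 ± 0.86). Cxcr1, a chemokine receptor of neutrophils, had no counts in ID saline and 28.5 ± 2.84 CPM in gel, at least 878-fold against a floor of 3 counts over the group. Tspan10 (20.5 ± 4.01 CPM, at least 631-fold) and Ocstamp, a gene of osteoclast fusion (9.77 ± 4.96 CPM, at least 301-fold), were also at 0 in saline. Chemokines have close paralogs, and how the counting shared reads between them is not given in the sources used here.

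The largest falls included several hair shaft genes. The hair keratin gene Kb23 fell from 14.7 ± 14.3 CPM to 0 (at least 479-fold). Krtap3-1 fell from 6.67 ± 5.35 (at least 217-fold), Krt34 from 4.86 ± 4.78 (at least 158-fold) and Krtap1-1 from 4.26 ± 3.83 (at least 139-fold), each to 0. Krtap8-1 fell from 17.5 ± 21.4 to 0.0239 ± 0.0586 CPM and Ly6g6g from 7.35 ± 3.23 to 0.0133 ± 0.0326. Keratins and keratin-associated proteins form families of similar sequence, so the level of any single member is less certain than that of the family.

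Of the immune lists 6 rose and the mast cell list fell. Of 24 tested macrophage genes, 21 rose and none fell (median 3.23 log2 units, adjusted p = 1.34e-07 by camera), among them Mpeg1, a pore-forming protein of macrophages, from 54.4 ± 13 to 2680 ± 257 CPM. Of 19 genes of macrophage fusion and the foreign-body response, 18 rose (median 3.12, adjusted p = 3.81e-07), including Mmp12, a macrophage elastase, by 9.65 ± 0.79, and Dcstamp, at 7.4 ± 3.59 CPM from 0 (at least 228-fold). In the inflammatory cytokine list 21 of 24 rose and 1, Il23a, fell by 1.25 ± 0.37 (median 3.26, adjusted p = 2.46e-06), with Ccl2 up by 7.98 ± 0.50 log2 units. Of 23 interferon response genes 21 rose (median 2, adjusted p = 3.02e-06), with Cxcl10 up by 5.19 ± 0.65. Of 16 antigen presentation genes 15 rose and 1 fell (median 1.43, adjusted p = 4.68e-05), with Tap1 up by 2.45 ± 0.16. Of 14 genes of alternative macrophage activation 10 rose and 2 fell (median 1.46, adjusted p = 0.0281), with Folr2 up by 2.80 ± 0.24 and the chemokine Ccl24 at -2.09 ± 0.29. For each of these 6 lists adjusted p = 0.49 with an estimated correlation, and camera called no list in any comparison when the correlation was estimated, where fry called 27, 17, 27 and 2 in the 4 comparisons.

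In the panel fixed beforehand, the macrophage genes Arg1 and Mrc1 rose by 1.74 ± 0.20 and 1.48 ± 0.20 log2 units, and the cytokine Il1b by 1.32 ± 0.23. Il4 had 0 counts in all libraries. Cd3e, a part of the T cell receptor complex, was at 2.25 ± 0.87 CPM in gel and 1.62 ± 0.576 in saline (0.48 ± 0.28, adjusted p = 0.129). In the T cell list 9 of 15 genes rose and 1 fell (median 1.34, adjusted p = 0.0515 by camera). Over the other settings its adjusted p ran from 1.38e-07, by fry, to 0.494, and in some of them the list was called. Cd8b rose by 6.34 ± 0.50 and Cd8a by 5.63 ± 0.62. Of 12 neutrophil genes 6 rose, such as Lcn2 by 4.56 ± 0.34, and 3 fell, such as Cxcr2 by 0.74 ± 0.18 (median 1.35, adjusted p = 0.112). Of 11 type 2 response genes 7 rose, Il1rl1 by 2.24 ± 0.22, and 2 fell, Gata3 by 2.48 ± 0.28 (median 1.33, adjusted p = 0.161). Mast cell genes fell, 9 of 12 with 1 rise (median -1.27, adjusted p = 0.00857, and adjusted p = 0.494 with an estimated correlation), and Cpa3, a mast cell protease, fell by 1.70 ± 0.22.

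Matrix genes moved in both directions at this site. Of 22 genes for collagen processing and crosslinking 19 rose and none fell (median 0.98, adjusted p = 2.34e-05, and adjusted p = 0.49 with an estimated correlation). Plod2, a lysyl hydroxylase, rose by 3.22 ± 0.23, P4ha3, a prolyl hydroxylase subunit, by 3.96 ± 0.35, and Lox, which crosslinks collagen, by 1.02 ± 0.13 log2 units from 111 ± 21.9 to 225 ± 23.6 CPM (adjusted p = 3.81e-07). The interstitial collagens themselves split, with 4 of 18 higher, 2 lower and 12 not called, or 3 and 2 adjusted over the list alone (median 0.25, adjusted p = 0.68). Col5a3 rose by 2.59 ± 0.20 and Col11a1 fell by 3.00 ± 0.35. Col1a1 stood at 16300 ± 7330 CPM in gel and 16600 ± 4590 in saline (-0.03 ± 0.27, adjusted p = 0.929) and Col1a2 at 9800 ± 4060 and 10000 ± 2700 (-0.04 ± 0.26, adjusted p = 0.908). Col1a1 averaged 10900 CPM in gel replicates 1 to 3 and 21600 in 4 to 6.

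Col3a1 was called higher at 14800 ± 4330 against 10200 ± 3040 CPM (0.55 ± 0.23, adjusted p = 0.0375). That call ended without ID gel 4 (0.45, adjusted p = 0.0937), ID gel 5 (0.42, 0.106), ID saline 2 (0.51, 0.0671), ID saline 3 (0.46, 0.0866) or ID saline 4 (0.45, 0.0907). Tgfb1 rose by 2.81 ± 0.20 from 29.1 ± 6.45 to 204 ± 39 CPM, and Fn1, which encodes fibronectin, by 2.57 ± 0.29, whereas Postn fell by 1.17 ± 0.25. In the activated fibroblast and TGF-beta list 11 of 26 rose and 9 fell (median 0.07, or -0.18 by FPKM, adjusted p = 0.609). Acta2, the smooth muscle actin also made by myofibroblasts, fell by 0.83 ± 0.20. Of 16 elastic fibre genes 4 rose, Emilin1 by 3.16 ± 0.14, and 8 fell, Fbn2 by 1.85 ± 0.35 (median -0.23, adjusted p = 0.614), and of 18 basement membrane genes 4 rose and 10 fell (median -0.98, adjusted p = 0.0723). Of 16 metalloproteinase and inhibitor genes 9 rose and 2 fell (median 0.55, adjusted p = 0.101), with the inhibitor Timp1 up by 4.10 ± 0.20.

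Several lists of resident skin structures fell. All 25 tested epidermal keratinocyte genes fell (median -1.89, adjusted p = 1.34e-07), and Ivl, a part of the cornified envelope, fell by 3.66 ± 0.32. Of 34 hair genes 32 fell and 1 rose (median -5.77, adjusted p = 1.34e-07), and of 18 sebaceous gland genes 13 fell (median -1.80, adjusted p = 0.000421), where Mc5r fell by 3.09 ± 0.31. Smooth muscle genes fell, 11 of 13 (median -1.42, adjusted p = 0.000421), and Lmod1 fell by 3.46 ± 0.27. For these 4 lists adjusted p = 0.49 with an estimated correlation. Of 28 skeletal muscle genes 27 fell, or 28 adjusted over the list alone (median -4.15, adjusted p = 2.56e-06, and adjusted p = 0.494 with an estimated correlation). Myh7, the slow myosin heavy chain, fell by 8.11 ± 1.00 from 766 ± 106 to 2.75 ± 5.13 CPM. The muscle enzyme gene Ckm, chosen after its values were seen, ranged from 0.0598 to 1290 CPM over the ID gel libraries and averaged 4930 ± 768 in saline. Muscle regeneration genes fell as well, 7 of 10 with no rise (median -2.69, adjusted p = 0.0101, and adjusted p = 0.494 with an estimated correlation).

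**Figure D2:**
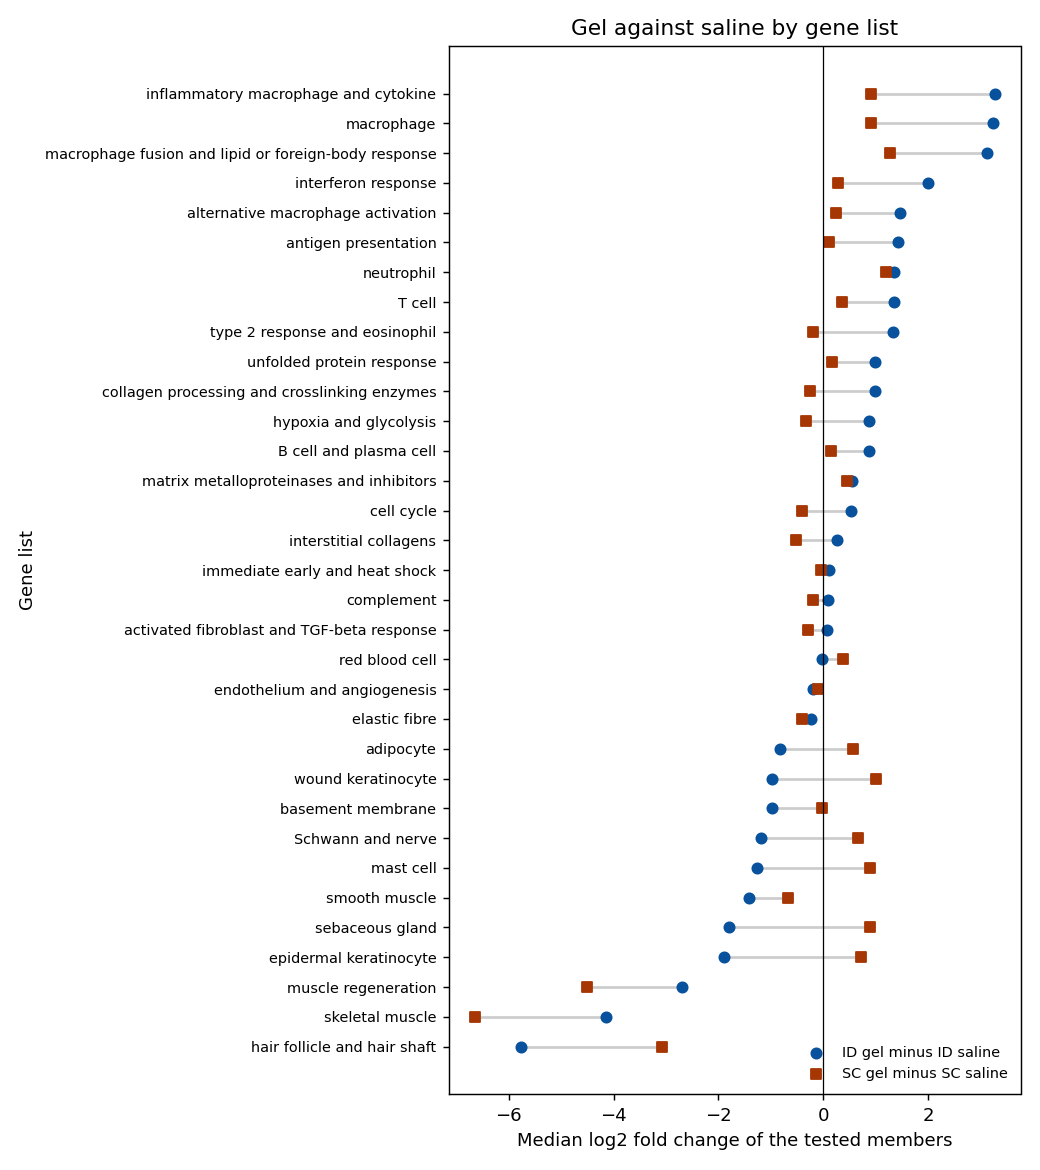
Median log2 fold change (x axis) of the tested members of each of the 33 gene lists (y axis), for ID gel minus ID saline (circles) and SC gel minus SC saline (squares), 6 libraries per group.

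The second comparison, SC gel against SC saline, asked how skin responded to gel placed under the dermis. Genes of macrophages and of their fusion rose, mast cell and epidermal genes rose, and muscle and hair genes fell. For these lists adjusted p was 0.604 to 0.832 with an estimated correlation. Cd68 rose by 2.35 ± 0.36 log2 units from 42.2 ± 9.76 to 216 ± 160 CPM (5.11-fold, adjusted p = 1.27e-05). Nos2 rose by 1.52 ± 0.49 from 1.13 ± 0.537 to 3.32 ± 2.72 CPM (adjusted p = 0.0124), with 0.53 in gel replicates 1 to 3 and 2.14 in 4 to 6. Of the tested genes 7504 changed (50.8%), 3652 higher and 3852 lower, and 920 rose and 1244 fell by at least 1 log2 unit. Without SC saline 2, which had the lowest TMM factor (0.845), the split was 4885 higher and 2692 lower. By deposited FPKM 74.6% of the changed genes were higher, against 48.7% by counts with TMM factors. The median change of all genes was 0.19 by FPKM and 0 by TMM, so small changes in either direction depended on the scaling.

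The largest rises included Wfdc18 and a gene beside it that the file names Anos1, both on chromosome 10. Wfdc18 (68588818 to 68589671), a member of the whey acidic protein family, reached 366 ± 174 CPM from 1.96 ± 2.42 (7.56 ± 0.68 log2 units). Anos1 (68561954 to 68562801) was at 13.1 ± 7.75 CPM in gel and at 0 in saline, at least 428-fold. Tyrp1, a melanosome enzyme, was at 15.2 ± 4.05 CPM in SC gel and 0.00851 ± 0.0209 in SC saline. Mmp12 rose by 7.80 ± 0.79 from 0.165 ± 0.0988 to 39.2 ± 39.5 CPM. Cxcr1 (2.19 ± 2.17 CPM, at least 71.4-fold) and Ocstamp (2.38 ± 2.55 CPM, at least 77.8-fold) again had no counts in saline. Against ID saline the rises of Wfdc18, Anos1 and Tyrp1 were smaller, at 4.31, 5.35 and 2.62 log2 units.

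The largest falls included several muscle genes. The slow muscle gene Myh7 fell by 10.33 ± 1.27 log2 units from 119 ± 103 to 0.0803 ± 0.132 CPM, and Myl2 fell by 9.95 ± 1.19 from 45.1 ± 34.2 to 0.0347 ± 0.0629. Actn3, an actinin of fast fibres, fell by 9.47 ± 1.55 from 3410 ± 1360 to 4.77 ± 8.15 CPM and Mybpc2 by 9.04 ± 1.51. Aqp4, a water channel present in fast fibres, fell by 9.76 ± 0.98, and Lrrc30 fell from 26.8 ± 10.6 to 0.0173 ± 0.0424 CPM. All 28 tested skeletal muscle genes fell (median -6.64, adjusted p = 2.96e-13, and adjusted p = 0.604 with an estimated correlation). In gel replicates 1 to 3 that median was -5.84, and in gel replicates 4 to 6 it was -11.61. The muscle enzyme gene Ckm, chosen after its values were seen, was at 0 to 0.172 CPM in gel replicates 4 to 6, against 5660 ± 2620 in saline. Of 10 muscle regeneration genes 8 fell and 1 rose, or 9 fell adjusted over the list alone (median -4.5, adjusted p = 0.000101, and adjusted p = 0.604 with an estimated correlation), and Myod1, a master regulator of muscle cells, fell by 6.62 ± 0.86. The rise was in Myh8 (3.50, adjusted p = 0.0458), at 576 CPM in SC gel 1, 120 in SC gel 3 and at most 0.572 in the others. That call ended without SC gel 1 (1.28, adjusted p = 0.425) and without several other libraries, and limma voom turned the value to -2.74. Smooth muscle genes fell, 7 of 13 (median -0.68, adjusted p = 0.00839, and adjusted p = 0.832 with an estimated correlation). Acta2 itself was at 210 ± 29.3 and 241 ± 62.4 CPM (-0.20 ± 0.20, adjusted p = 0.427).

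Among immune lists the fusion and foreign-body list rose most evenly, in 18 of 19 genes (median 1.26, adjusted p = 2.23e-11), with Dcstamp, needed for macrophages to fuse, at 2.96 ± 2.91 CPM from 0.0214 ± 0.0524. The list also holds lipid genes such as Plin2, Cd36 and Lpl, so it does not measure macrophages alone. Lpl is in the adipocyte list too, where 9 of 20 genes rose at this site and 2 fell (median 0.57, adjusted p = 0.0648 by camera). Of 24 macrophage genes 14 rose, such as Mpeg1 by 2.66 ± 0.39 and Cybb by 2.30 ± 0.37, and 2 fell, Siglec1 by 1.22 ± 0.26 and Adgre1 by 0.76 ± 0.17 (median 0.9, adjusted p = 0.00886). In the inflammatory cytokine list 11 of 24 rose, or 9 adjusted over the list alone (median 0.9, adjusted p = 0.00283), with Ccl2 up by 4.18 ± 0.43. Of 12 neutrophil genes 8 rose and 1, Mpo, fell by 2.24 ± 0.42 (median 1.19, adjusted p = 0.0362). Mast cell genes rose, 8 of 12, or 11 adjusted over the list alone (median 0.88, adjusted p = 0.000595), with the tryptase Tpsab1 up by 2.00 ± 0.23. With an estimated correlation adjusted p = 0.604 for the fusion, cytokine and mast cell lists, adjusted p = 0.832 for macrophage genes and adjusted p = 0.636 for neutrophil genes.

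Camera called none of the other immune lists at this site. In the panel Il1b rose by 1.02 ± 0.23, Arg1 by 0.94 ± 0.20 and Tgfb1 by 0.74 ± 0.19, while Mrc1 (354 ± 77.8 against 293 ± 32 CPM, 0.27 ± 0.19, adjusted p = 0.245) and Cd3e (1.74 ± 0.479 against 2.03 ± 0.458 CPM, -0.22 ± 0.28, adjusted p = 0.53) were not called. Of 23 interferon response genes 6 rose, Cxcl10 by 2.88 ± 0.65 (median 0.28, adjusted p = 0.265). The median of the interferon list was -0.13 in gel replicates 1 to 3 and 0.61 in 4 to 6. Against ID saline 15 interferon response genes rose in SC gel (median 0.68). Of 15 T cell genes 4 rose, Cd8b by 2.93 ± 0.48, and 3 fell, Foxp3 by 1.51 ± 0.35 (median 0.36, adjusted p = 0.398). Of 14 genes of alternative macrophage activation 5 rose and 1 fell, or 4 and 1 adjusted over the list alone (median 0.24, adjusted p = 0.348). Antigen presentation genes split, with 5 of 16 higher, such as Nlrc5 by 0.77 ± 0.15, and 5 lower, such as Cd74 by 0.59 ± 0.13. The median of that list was 0.1 and its mean -0.02, and its test pointed up (adjusted p = 0.928).

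Epidermal keratinocyte genes rose, 14 of 25 with 1 fall, or 15 and 1 adjusted over the list alone (median 0.71, adjusted p = 0.00062, and adjusted p = 0.832 with an estimated correlation). Krt10, a keratin of the upper epidermis, rose 2.83-fold from 2090 ± 345 to 5930 ± 875 CPM, while Ivl fell by 1.61 ± 0.28. Sebaceous gland genes rose, 11 of 18 with 2 falls (median 0.89, adjusted p = 0.0116, and adjusted p = 0.832 with an estimated correlation), with the lipid desaturase Scd up by 1.71 ± 0.20. Both rises were smaller against ID saline. There the epidermal median was 0.33, with 11 genes higher and 1 lower, and the sebaceous median 0.47, with 7 higher and 4 lower. Schwann cell and nerve genes rose, 11 of 15 with none lower (median 0.66, adjusted p = 0.00408, and adjusted p = 0.604 with an estimated correlation), with the myelin gene Mbp up by 0.93 ± 0.14. Hair genes fell, 26 of 34 with none higher (median -3.08, adjusted p = 2.13e-10, and adjusted p = 0.604 with an estimated correlation). The mean log2 CPM of that list was 3.59 in SC gel 3 and -1.15 to 0.34 in the other SC gel libraries. Shh, a signal of growing hair follicles, fell by 5.48 ± 0.50. Cell cycle genes fell, 11 of 26 (median -0.4, adjusted p = 0.0213, and adjusted p = 0.832 with an estimated correlation), and Mki67 fell by 1.11 ± 0.26. By FPKM only 5 of 25 cell cycle genes fell and 1 rose (median -0.1).

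The 3 collagen genes of the panel were lower in SC gel than in SC saline. Col3a1 fell by 1.02 ± 0.23 log2 units from 24000 ± 4180 to 11800 ± 3620 CPM (adjusted p = 0.000901), Col1a1 by 0.87 ± 0.27 from 36200 ± 8340 to 19800 ± 6590 (adjusted p = 0.0101) and Col1a2 by 0.75 ± 0.26 (adjusted p = 0.0191). The Col1a2 call ended without SC gel 2 (adjusted p = 0.0565), SC gel 3 (adjusted p = 0.0557), SC saline 1 (adjusted p = 0.0535) or SC saline 2 (adjusted p = 0.0721). Of 18 interstitial collagens 9 fell and 1, Col8a1, rose by 1.51 ± 0.19 (median -0.53, adjusted p = 0.0619 by camera). Over the other settings the adjusted p of this list ran from 0.0204, by fry, to 0.832, and in some of them it was called. Of 22 collagen processing genes 3 rose and 7 fell (median -0.25, adjusted p = 0.265), and Lox was at 151 ± 30.1 and 141 ± 19.4 CPM (0.10 ± 0.13, adjusted p = 0.554). Of 16 elastic fibre genes 2 rose, Eln by 0.63 ± 0.19, and 9 fell (median -0.41, adjusted p = 0.0608 by camera). Over the other settings the adjusted p of this list ran from 0.00602, by fry, to 0.832, and in some of them it was called. The falls of the collagens depended on the saline group. Against ID saline the SC gel values were 0.25 for Col1a1, 0.26 for Col1a2 and 0.22 for Col3a1, none of them called, and against SC saline Col1a1 and Col3a1 in ID gel fell by 1.15 and 0.69.

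**Figure D3:**
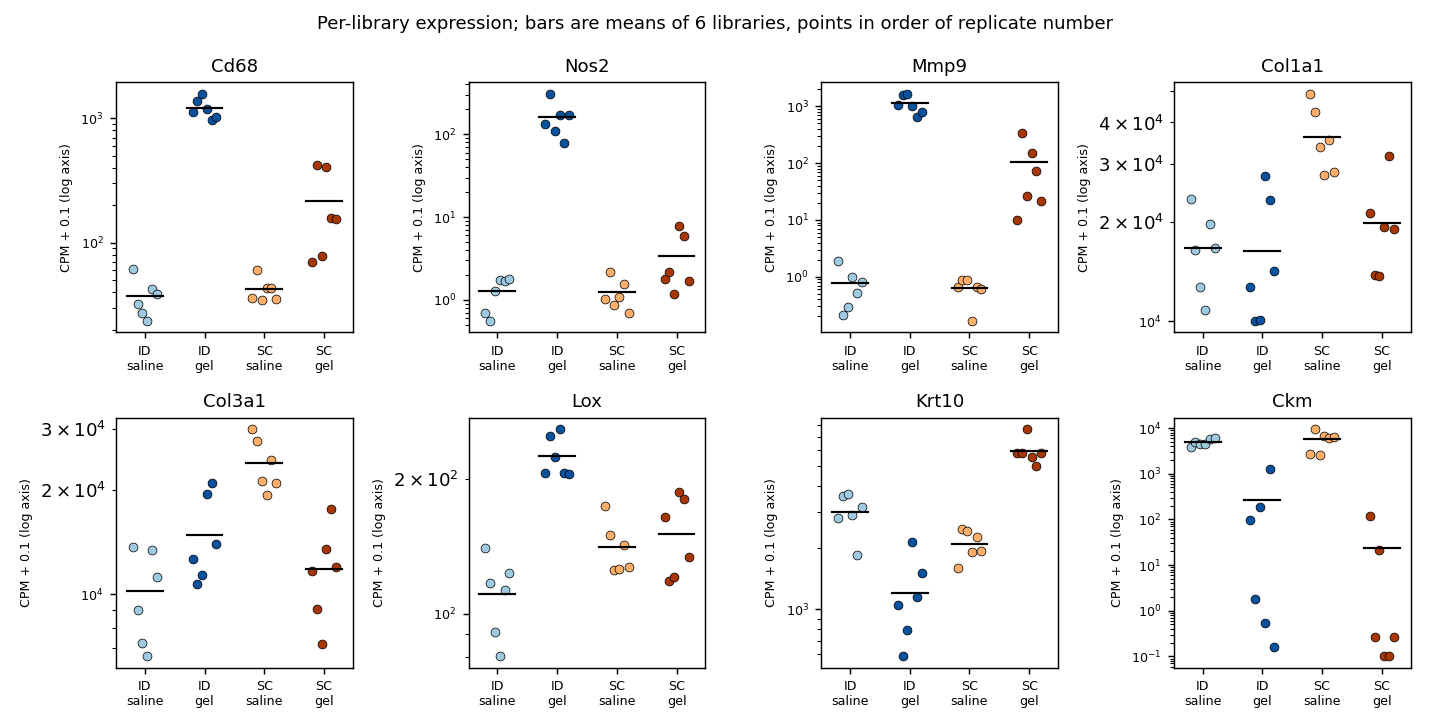
Expression of 8 genes in each library (y axis, CPM + 0.1 on a log scale) by group (x axis), with bars at the means of 6 libraries, for example 1210 CPM for Cd68 in ID gel and 216 in SC gel.

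The third comparison, the ID effect minus the SC effect, asked where the response to gel differed between sites. Macrophage, cytokine and collagen enzyme genes had the more positive effect in the dermis, and epidermal, mast cell and sebaceous genes the more positive effect under it. For these lists adjusted p was 0.221 to 0.366 with an estimated correlation. The effect on Nos2 was larger at ID by 5.58 ± 0.71 log2 units (adjusted p = 8.25e-07), that on Cd68 by 2.66 ± 0.50 (adjusted p = 9.12e-05) and that on Tgfb1 by 2.07 ± 0.27 (adjusted p = 9.06e-07). The effect differed for 8234 genes, 4845 more positive at ID and 3389 at SC, and by at least 1 log2 unit for 1985 and 2114. Of the genes that differed, 31.8% were more positive at ID by FPKM, against 58.8% by TMM, and the median difference of all genes was -0.2 by FPKM and 0.12 by TMM. Without SC saline 2 the split was 3689 and 4095.

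Among the genes changed in both comparisons, 2223 were higher at both sites, where 1336 would be expected if the calls were independent, and 2581 were lower at both (1427 expected). A further 385 were higher at ID and lower at SC, and 823 the reverse. Of the genes higher at both sites 1525 had a different effect, larger at ID for 1480, and of those lower at both 730 did, larger at ID for 565. Across all tested genes the effects at both sites correlated with r = 0.619.

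Among called genes with a symbol and a mean log2 CPM of at least 1, the most ID-directed effects were in Msln, Fgf23, Slc16a3, Psca and Ccl3. Msln, which encodes mesothelin, was at 106 ± 39.4 CPM in ID gel and 1.09 ± 0.708 in SC gel (difference of effects 7.15 ± 0.68), and Fgf23, a phosphate-regulating hormone made in bone, at 11.7 ± 9.3 and 0.0743 ± 0.0593 (6.73 ± 1.10). The lactate transporter Slc16a3 was at 193 ± 61 and 3.45 ± 2.13 CPM (6.12 ± 0.57), Psca at 220 ± 78.8 and 5.49 ± 6.32 (6.06 ± 1.19), and Ccl3 at 39.5 ± 13.4 and 2.43 ± 2.36 (5.83 ± 1.44). Mmp9 (3.15, adjusted p = 0.0197) and Ccl9 (3.51 ± 1.42) also had larger effects at ID. The call for Ccl9 ended without ID gel 2 (3.34), ID gel 3 (3.22), ID saline 2 (3.30), ID saline 4 (3.38), SC saline 1 (3.35) or SC saline 2 (3.22). For Acod1 (6.23 ± 3.66, adjusted p = 0.151), Tspan10 (4.31 ± 3.96, adjusted p = 0.368), Mmp12 (1.84 ± 1.64, adjusted p = 0.349) and Ly6g6g (-2.63 ± 1.75, adjusted p = 0.206) edgeR called no difference, nor for Cxcr1 and Ocstamp, which had no counts in either saline group, while DESeq2 and limma voom called Acod1 and Tspan10.

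In the other direction Anos1 (-8.71 ± 1.57), Tyrp1 (-7.64 ± 1.42) and Wfdc18 (-6.21 ± 0.80) had the more positive effect at SC. With the saline groups exchanged all 3 turned, to 1.99 for Anos1, 6.51 for Tyrp1 and 0.28 for Wfdc18. The hair genes Krtap3-1 (-8.45 ± 2.88), Kb23 (-8.39 ± 3.41), Krt34 (-7.91 ± 3.09) and Krtap8-1 (-7.79 ± 3.16) were called too, but the calls rested on SC gel 3, and those of Kb23, Krt34 and Krtap8-1 ended without several other libraries too. Without SC gel 3 they were -5.61 (adjusted p = 0.089), -5.64 (adjusted p = 0.207), -5.15 (adjusted p = 0.174) and -4.20 (adjusted p = 0.318). Fitted values of genes at 0 in a group depend on the prior count and are no bound. Krtap3-1 was at 11.7 CPM in SC gel 3 and at 0 to 0.779 in the other SC gel libraries. Among hair genes as a list 14 of 34 were lower and 2 higher, or 13 and 2 adjusted over the list alone (median -2.39, adjusted p = 0.0827). The median of the hair list was -3.08 with gel replicates 1 to 3 and 0.07 with gel replicates 4 to 6. Of 28 muscle genes 3 were called higher at ID, or 1 adjusted over the list alone (median 2.78, adjusted p = 0.769). The median of the muscle list was 0.56 with gel replicates 1 to 3 and 8 with gel replicates 4 to 6. Without ID gel 5 the difference for Actn3 went from 5.10 to 2.76 (adjusted p = 0.0773) and that for Mybpc2 from 4.70 to 2.37 (adjusted p = 0.124).

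By list, the effect was more positive at ID for 20 of 24 macrophage genes (median 2.38, adjusted p = 3.45e-07), with Fcgr2b, an inhibitory antibody receptor, at 4.01 ± 0.31, and for 17 of 24 cytokine genes with 1 the reverse (median 2.65, adjusted p = 6.61e-05). Interferon response genes differed in 21 of 23 (median 1.81, adjusted p = 7.79e-06) and antigen presentation genes in 15 of 16 (median 1.3, adjusted p = 3.87e-06). In the fusion and foreign-body list 10 of 19 were more positive at ID, Trem2 by 3.09 ± 0.57, and 2 at SC, with Plin2, a lipid droplet coat protein, at 170 ± 20.2 CPM in ID gel and 384 ± 89.8 in SC gel (median 1.51, adjusted p = 0.0366). With an estimated correlation adjusted p = 0.366, 0.221, 0.487, 0.221 and 0.649 for these lists in turn. Collagen processing genes differed in 18 of 22, with 1 the reverse (median 1.34, adjusted p = 6e-07, and adjusted p = 0.288 with an estimated correlation), such as Plod2 by 3.99 ± 0.33 and Lox by 0.92 ± 0.19. Cell cycle genes differed in 23 of 26, with 1 the reverse (median 0.92, adjusted p = 0.00235, and adjusted p = 0.641 with an estimated correlation). By FPKM only 7 of 25 cell cycle genes were more positive at ID and 1 at SC (median 0.4).

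Of the collagens Col3a1 differed by 1.57 ± 0.33 (adjusted p = 0.000309), and Col1a1 (0.84 ± 0.38, adjusted p = 0.0646) and Col1a2 (0.71 ± 0.37, adjusted p = 0.101) were not called. With the saline groups exchanged the Col3a1 difference turned to -0.91, that of Col1a1 to -1.41 and that of Col1a2 to -1.30. Of 18 interstitial collagens 7 were more positive at ID and 1 at SC (median 0.68, adjusted p = 0.132). Mrc1 (1.21 ± 0.28) and Arg1 (0.80 ± 0.28) had larger effects at ID, and Il1b (0.30 ± 0.33, adjusted p = 0.453), Cd3e (0.70 ± 0.40, adjusted p = 0.137) and Acta2 (-0.64 ± 0.28, adjusted p = 0.0618) were not called.

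The effect was more positive at SC for all 25 epidermal keratinocyte genes (median -2.59, adjusted p = 3.65e-15), with Dsp, which encodes desmoplakin, at -2.92 ± 0.30. The same direction held for 15 of 18 sebaceous gland genes with 1 the reverse (median -2.77, adjusted p = 2.06e-07) and for 11 of 12 mast cell genes (median -2.14, adjusted p = 6.56e-07), with the chymase Cma1 at -2.38 ± 0.25. Schwann cell and nerve genes differed in 11 of 15 with 3 the reverse (median -1.74, adjusted p = 0.000497). For these 4 lists adjusted p = 0.221 with an estimated correlation. Adipocyte genes differed in 14 of 20, or 15 adjusted over the list alone (median -1.4, adjusted p = 0.000462, and adjusted p = 0.531 with an estimated correlation), with the fat hormone Adipoq at -2.14 ± 0.44. Wound keratinocyte genes differed in 10 of 15, or 11 adjusted over the list alone (median -2.08, adjusted p = 0.00165, and adjusted p = 0.487 with an estimated correlation). Basement membrane genes differed in 7 of 18 with 3 the reverse, or 8 and 3 adjusted over the list alone (median -0.56, adjusted p = 0.015, and adjusted p = 0.553 with an estimated correlation), and smooth muscle genes in 5 of 13, or 4 adjusted over the list alone (median -0.77, adjusted p = 0.0146, and adjusted p = 0.604 with an estimated correlation).

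The last comparison, ID saline against SC saline, asked whether the tissue differed without gel. It cannot tell site from any other difference between the saline libraries, such as tissue source, which would also enter the third comparison. For example, the gene ENSRNOG00000069434 was at 16.3 to 20.5 CPM in ID saline and 0 to 0.265 in SC saline. That gene also parted replicates 1 to 3 from 4 to 6 within each gel group. The interstitial collagen list was lower in ID saline (adjusted p = 7.15e-08, and adjusted p = 0.774 with an estimated correlation). Tyrp1 was at 2.5 ± 2.79 CPM in ID saline, from 222 counts, and at 0.00851 ± 0.0209 in SC saline, from 1 count. Wfdc18 was higher by 3.25 ± 0.60 log2 units (18.4 ± 12.1 against 1.96 ± 2.42 CPM) and Tnnt1, the slow muscle troponin T, by 2.52 ± 0.49. Inmt (-2.04 ± 0.36), the cadherin Cdh7 (-1.56 ± 0.30) and the transporter Abcg2 (-1.55 ± 0.25) were lower. Calls were made for 475 genes, 247 higher and 228 lower, 46 and 46 of them by at least 1 log2 unit, and by FPKM 70.8% were higher, against 52% by TMM. The count ranged from 132 without SC saline 2 to 888 without SC saline 5, and was 219, 146, 142 and 285 without ID saline 2, 3, 4 and 6 and 173, 305 and 237 without SC saline 1, 3 and 4. The calls for Tnnc1 (2.77 ± 0.70), Myl2 (2.46 ± 0.62), Ifit1 (-1.86 ± 0.51) and Hoxc11 (-1.72 ± 0.42) ended without SC saline 2 (adjusted p = 0.0904, 0.0863, 0.103 and 0.0839) and in most of the other refits.

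In the list tests 7 of 18 interstitial collagens were lower in ID saline, or 9 adjusted over the list alone (median -0.53, adjusted p = 7.15e-08), as were 8 of 22 collagen processing genes, or 13 adjusted over the list alone (median -0.31, adjusted p = 3.07e-10). Interferon response genes (1 of 23 lower, or 5 adjusted over the list alone, median -0.37, adjusted p = 2.39e-05), antigen presentation genes (1 of 16 lower, median -0.24, adjusted p = 0.000637) and red blood cell genes (6 tested, median -1.65, adjusted p = 0.00425) pointed the same way. Sebaceous gland genes pointed to higher levels in ID saline (2 of 18 higher, or 5 adjusted over the list alone, median 0.35, adjusted p = 0.0063). In the activated fibroblast list 1 of 26 was lower, or 2 higher and 5 lower adjusted over the list alone (median -0.26, adjusted p = 0.0137). With an estimated correlation adjusted p = 0.774 for each of these lists. Epidermal keratinocyte genes (25 tested, median 0.29, adjusted p = 0.00339) and wound keratinocyte genes (1 of 15 higher, median 0.88, adjusted p = 0.0245) pointed up in ID saline, and elastic fibre (1 of 16 lower, median -0.16, adjusted p = 0.0375), adipocyte (20 tested, median -0.37, adjusted p = 0.0137) and endothelial genes (1 of 22 lower adjusted over the list alone, median -0.22, adjusted p = 0.00425) pointed down. For these 5 lists adjusted p = 0.812 with an estimated correlation. Of 28 skeletal muscle genes 1 was higher, or 2 adjusted over the list alone (median 0.18, adjusted p = 0.256).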

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

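Of the tests in this part only the refits without single libraries and the exchange of the saline groups were chosen after the results were seen. In 11 of 188 groups of 6 libraries 1 library stood apart by Dixon's test, where chance gives about 5%. By mean log2 CPM of a list these were ID saline 1 for macrophage fusion (5.4, the others 5.06 to 5.14), SC saline 4 for alternative macrophage activation (4.35, others 4.56 to 4.6), SC gel 1 for mast cells (4.69, others 3.93 to 4.15), SC saline 5 for antigen presentation (5.35, others 4.97 to 5.1) and for immediate early genes (4.8, others 4.36 to 4.52), and SC gel 3 for hair (3.59, others -1.15 to 0.34). The others were SC saline 4 for sebaceous gland (5.94, others 5.37 to 5.51) and for Schwann cell genes (3.38, others 2.78 to 3), SC saline 1 for adipocytes (6.84, others 5.96 to 6.22) and ID gel 1 for the cell cycle (5.05, others 4.72 to 4.83). Among single genes Cd68 stood at 60.4 CPM in SC saline 2 and at 34.8 to 43.5 in the others.

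The response to gel differed between sites for 17 lists, here as median log2 differences, ID minus SC. With an estimated correlation camera called none of these 17 (adjusted p from 0.221 to 0.649), and fry called 27 of the 33 lists. More positive at ID were inflammatory cytokines (2.65), macrophages (2.38), interferon response (1.81), hypoxia and glycolysis (1.65), macrophage fusion (1.51), collagen processing (1.34), antigen presentation (1.3), unfolded protein response (0.95) and cell cycle (0.92). More positive at SC were sebaceous gland (-2.77), epidermal keratinocyte (-2.59), mast cell (-2.14), wound keratinocyte (-2.08), Schwann and nerve (-1.74), adipocyte (-1.4), smooth muscle (-0.77) and basement membrane (-0.56).

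It also differed for 21 of the named genes with the largest changes or in the panel. These were Nos2 (5.58), Actn3 (5.10), Lrrc30 (4.89), Mybpc2 (4.70), Aqp4 (4.50), Ccl9 (3.51), Mmp9 (3.15), Cd68 (2.66), Tgfb1 (2.07), Col3a1 (1.57), Mrc1 (1.21), Lox (0.92) and Arg1 (0.80) in the direction of ID. In the direction of SC they were Anos1 (-8.71), Krtap3-1 (-8.45), Kb23 (-8.39), Krt34 (-7.91), Krtap8-1 (-7.79), Krtap1-1 (-7.66), Tyrp1 (-7.64) and Wfdc18 (-6.21). The calls for Krtap3-1, Kb23, Krt34, Krtap8-1 and Krtap1-1 ended without SC gel 3 (-5.61, -5.64, -5.15, -4.20 and -3.71) and those for Actn3, Mybpc2, Lrrc30 and Aqp4 without ID gel 5 (2.76, 2.37, 2.61 and 2.43). The call for Ccl9 ended when any 1 of 6 libraries was left out (3.22 to 3.38). With the saline groups exchanged Anos1, Tyrp1, Wfdc18 and Col3a1 turned (1.99, 6.51, 0.28 and -0.91).

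Chance assignment of the libraries to groups is argued against for each of the 4 counts of genes. Of 100 splits only 1, the real split, gave as many. The splits treat the libraries as independent, which the labels do not show. Chance differences between animals or tissue sources are therefore not covered. The real counts were 10868, 7504, 8234 and 475, and the highest of the other splits gave 6849, 3785, 4284 and 208.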

How the results depend on the processing

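The settings with the saline groups exchanged, with gel replicates 1 to 3 or 4 to 6 alone, and the refits of named genes without single libraries were chosen after the results were seen, and the others were planned. A value turned when its direction changed and either fit called it. The tallies of named genes leave out the FPKM fits, the limit of 1 log2 unit and the refits without single libraries. Over the other planned settings 3535 values of named genes kept their direction and their side of the threshold, called or not. There 87 lost a call, 10 gained one and 1 turned, and over the added settings 1242, 133, 12 and 23 did. For lists the planned settings in the tally were an estimated correlation, fry, the replicate block and RLE factors. They gave 430 on the same side of the threshold, called or not, 68 calls lost and 30 gained. The added settings gave 263, 9 and 23, with 2 turned. Without 1 library at a time all calls held for 144 of 150 called named genes at ID, 128 of 152 at SC, 122 of 145 for the difference and 6 of 10 for saline. The causes of these changes were not tested. With the replicate block the counts of genes were 10918, 7542, 8250 and 529, but libraries of the same number did not all deviate together. After subtracting group means, their correlation between ID gel and SC gel ran from -0.13 to 0.42, with 4 of 6 over 0.1 and 3 of 6 best with their own number, and between the saline groups from -0.12 to 0.38, with 4 and 2. Blocking moved the interstitial collagen and elastic fibre lists at SC to an adjusted p of 0.0453 each.

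With a limit of 1 log2 unit 5280, 2164, 4099 and 92 genes remained. Between the saline groups the DESeq2 Wald test called 1021 genes, limma voom with quality weights 1600 and edgeR without a filter 316, and leaving out 1 library gave 132 to 888. Leaving out 1 library gave 10587 to 10941 at ID, 7101 to 7577 at SC and 7784 to 8437 for the difference. With an estimated correlation camera called 0 lists in each contrast, and fry called 27 at ID, 27 for the difference and 2 between saline groups. The correlation of effects, 0.619, became 0.624 over genes changed at either site, 0.66 over genes with a mean log2 CPM of at least 3, 0.575 and 0.636 with gel replicates 1 to 3 and 4 to 6 alone, and 0.64 with the saline groups exchanged.

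With the saline groups exchanged these values turned. At ID it was Col3a1 (-0.69). At SC they were Col1a1 (0.25), Col1a2 (0.26), Col3a1 (0.22), Mfap2 (0.18), Adamts4 (0.0938) and Il13ra2 (0.35). For the difference they were Anos1 (1.99), Tyrp1 (6.51), Wfdc18 (0.281), Col1a1 (-1.41), Col1a2 (-1.30), Col3a1 (-0.91), Col5a1 (-0.62), Vsig4 (-0.62), Cd9 (0.18), S100a9 (0.64), S100a8 (0.36) and Pmp22 (-0.21), and the interstitial collagen list turned with an adjusted p of 0.0384. With gel replicates 1 to 3 alone Cd79a (-0.14) and Ahsp (-2.85) turned at SC. With gel replicates 4 to 6 alone Myh8 turned at SC (-5.66), Krtap8-1 for the difference (0.0143) and the red blood cell list at SC (adjusted p = 0.0478). With limma voom Myh8 turned at SC (-2.74).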

Other observations

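The tests of causes in this part were chosen after the results were seen, and the list tests before. Stress and metabolic genes not described above also moved with gel. In the unfolded protein response list all 17 tested genes rose in ID gel (median 0.98, adjusted p = 1.1e-06, and adjusted p = 0.49 with an estimated correlation), with Ddit3, a transcription factor of that response, up by 2.18 ± 0.18 log2 units, while in SC gel 5 rose and 4 fell (median 0.17, adjusted p = 0.605). The effect was more positive at ID for 16 of 17, or 17 adjusted over the list alone (median 0.95, adjusted p = 5.04e-07, and adjusted p = 0.221 with an estimated correlation). In the hypoxia and glycolysis list 13 of 20 rose in ID gel and 1 fell (median 0.87, adjusted p = 0.00266, and adjusted p = 0.49 with an estimated correlation), and in SC gel 5 rose and 9 fell (median -0.33, adjusted p = 0.114). Slc2a1, a glucose transporter, rose at both sites, by 3.86 ± 0.18 at ID and 1.18 ± 0.16 at SC, and the glycolytic gene Eno1 by 2.69 ± 0.16 and 0.72 ± 0.15. Gapdh fell by 0.80 ± 0.19 and 2.97 ± 0.21, and Tpi1 fell by 2.40 ± 0.19 at SC, beside the skeletal muscle genes that fell at both sites.

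Among smaller groups, 6 of 16 complement genes rose in ID gel and 3 fell, or 6 and 2 adjusted over the list alone (median 0.09, or -0.01 by FPKM, adjusted p = 0.514), with C3 up by 3.67 ± 0.33, and 4 of 6 B cell genes rose (median 0.86, adjusted p = 0.161), with Fcrla at 21.8 ± 4.51 against 0.539 ± 0.232 CPM. Of 22 endothelial genes 6 rose and 8 fell in ID gel (median -0.19, adjusted p = 0.674), with Tie1 up by 1.72 ± 0.13, whereas Vwf fell by 1.15 ± 0.24. In the immediate early list Atf3 rose by 3.72 ± 0.41 and Nr4a1 fell by 2.98 ± 0.26, with 5 of 15 higher and 4 lower (median 0.10, or -0.05 by FPKM, adjusted p = 0.916). Mmp13, a collagenase, rose at SC by 4.96 ± 0.80 from 0.211 ± 0.175 to 6.78 ± 5.62 CPM and its effect was more positive at SC than at ID by 4.70 log2 units (-4.70 ± 1.09, adjusted p = 0.000788). The red blood cell list had a median of 0.37 in SC gel while its test pointed down (adjusted p = 0.694). Against SC saline the median of that list was -2.75 in SC gel replicates 1 to 3 and 1.3 in replicates 4 to 6.

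Replicates 1 to 3 and 4 to 6 parted in the same direction in both gel groups for 53 genes, 42 of them higher in 4 to 6, with at most 21 in any other pair of splits. Of these genes 50 differed between SC saline and ID saline in the direction in which replicates 4 to 6 differed from 1 to 3, 8 of 8 among those called between the saline groups. The gene with the Ensembl identifier ENSRNOG00000069434 was at 16.3 to 20.5 CPM in ID saline, 38.5 to 41.8 and 27.3 to 36.8 in ID and SC gel replicates 1 to 3, and at most 0.265, 0.131 and 0.58 in SC saline and in gel replicates 4 to 6, and Ccdc77, Ces2b and Afg3l1 split the same way. A difference in library size is argued against, since the mean totals of both sets of replicates differed by at most 0.065 log2 units. Blood left in the tissue could not be told apart for the genes higher in 4 to 6, of which 26 of 42 followed the red blood cell list within the saline groups. It is argued against for the 11 lower genes, of which 1 followed that list, and whose medians in 4 to 6 against 1 to 3 were -1.90 in ID gel and -1.78 in SC gel, with a median of 0 and -0.01 over all tested genes. A hypothesis is that the libraries came from a pair of tissue sources, with ID saline and gel replicates 1 to 3 from one, and SC saline and gel replicates 4 to 6 from the other, in which case the saline groups may differ by source as well as by site.

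Of 18 interstitial collagens 9 were called lower in SC gel than in SC saline, and the list had an adjusted p of 0.0619 by camera. Over the other settings this ran from 0.0204, by fry, to 0.832, and in some of them the list was called. Against ID saline 2 collagens were lower, so the number of falls depended on the saline group. Collagens were already seen to be lower in ID saline than in SC saline, and this count restates that difference. It does not test whether the difference was of site or of source. A fall in only 1 set of replicates is argued against by the median of the set with the smaller fall, -0.45. An exchange of the saline labels, which bears on every result by site, could not be told apart, since no gene known beforehand to mark the site was at hand. The table sets ID saline beside SC gel. Without overlap 22 genes parted ID saline and SC gel from SC saline and ID gel, and 13 parted ID from SC as labelled. A further count, of genes parting saline from gel, was 1826. Without a gene that marks the site these counts do not decide the question. As a hypothesis, the fall of collagen under the dermis may rest in part on a high level in SC saline, and if the sources are as supposed above, the matched comparisons are SC gel replicates 4 to 6 against SC saline (Col1a1 -0.62, Col1a2 -0.51, Col3a1 -0.73) and ID gel replicates 1 to 3 against ID saline (Col1a1 -0.60, Col1a2 -0.56, Col3a1 0.19).

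Of 8 resident lists 5 fell in ID gel (epidermal, hair, sebaceous, smooth and skeletal muscle, adjusted p of 0.49 to 0.494 with an estimated correlation), and skeletal muscle fell at both sites. Camera did not call the adipocyte list (13 of 20 fell), the Schwann cell list (10 of 15 fell) or the endothelial list (8 of 22 fell), and fry called the adipocyte and Schwann cell lists. Dilution by incoming cells alone would lower all resident genes alike, but the medians of the resident lists lay 5.58 log2 units apart, from -5.77 for hair (quartiles -7.43 and -4.03) to -0.19 for endothelium (quartiles -0.69 and 0.52). That 27 of 28 muscle genes were lower at both sites restates the pattern and decides nothing about less skeletal muscle in the sampled tissue. Whether muscle under the skin was lost in the animal or was left out when the tissue around the gel was taken is open, and no table here decides it. A hypothesis to test by histology is that hair follicles and the muscle layer may be displaced or lost around the gel.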
